A study of Mus musculus with 4 samples.

How the data were processed

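RNA of testis tissue from FVB mice was sequenced in 4 libraries, 2 labelled as mutant for Lrrc8a (MUT) and 2 as wild type (WT). Per the labels' protocols, freshly isolated testis was extracted with Trizol, treated with DNase I and turned into libraries with the Illumina TruSeq stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. The labels give the cell type as germ cells but the source as testis, and name no step that separates cells, so the libraries are treated as whole tissue. Whether the libraries of a genotype came from separate animals is not stated in the sources used here, so p-values measure the spread between these libraries, which may be technical. The kind of mutation is not stated there either.

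The authors deposited a single table of CPM, read counts scaled to the size of each library, for 24420 gene symbols. Per the submitters' processing notes, TopHat2 2.0.10, HTSeq 0.6.0, edgeR 3.8.6 and the mouse build mm10 were used. The notes give these names without their roles or order, and the strand setting of the counting is not given in the sources used here. The deposited CPM columns sum to 992486.9 and 987722.6 in MUT 1 and MUT 2, and to 1011463 and 1008533 in WT 1 and WT 2, which is the pattern of CPM divided by scaled library sizes. Every value is a whole multiple of the smallest value in its library: 100% lay within 0.001 of a whole read. This recovered 48409785 and 40426400 reads in MUT 1 and MUT 2, and 68192776 and 50162558 in WT 1 and WT 2. A floor of 3 reads corresponds to 0.0615, 0.0733, 0.0445 and 0.0603 CPM in MUT 1, MUT 2, WT 1 and WT 2, and covers counting error only. Of the symbols, 3133 are at 0 in all libraries.

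The main test used the deposited CPM with no further scaling. Symbols with a CPM of at least 1 in at least 2 libraries were kept, and log2(CPM + 0.5) was tested with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(CPM + 0.5) scale, MUT minus WT, and understate the change of weakly expressed genes. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so single genes were tested only within the model fitted across all genes. The median standard error of a log2 fold change was 0.0948. For 25 gene lists, 23 of which had at least 3 tested members, limma's camera was run with a preset correlation between genes of 0.01, and again with an estimated correlation. Camera compares a list with the other genes. The rotation test fry, run beside it, asks only whether the members of a list change. With an estimated correlation, camera uses only the residual degrees of freedom, which are few with 2 libraries per genotype. A list that it does not call is therefore weak evidence against a shift. An estimated correlation above the preset 0.01 also raises p. It was 0.41 for the peritubular myoid, 0.108 for the Leydig, 0.0489 for the Sertoli and 0.0237 for the elongating spermatid list. Calls of these lists at the preset correlation are therefore not secure.

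The genes to be named, the lists, the tests and most alternatives were fixed before the data were examined. The rule took the LRRC8 family, the 12 genes with the largest called change in each direction that had a mean of at least 2 CPM in the higher group, no overlap between the groups and no predicted or clone name, and up to 4 members with the smallest p from each list. For germ cell stages, Sertoli, Leydig and macrophage lists it also took the member with the highest mean CPM. Genes outside it are said to be chosen after their values were seen. Gene positions are 1-based and come from GENCODE vM21 on GRCm38, the build called mm10, and from RefSeq where GENCODE had no match. GENCODE names matched 23328 symbols, RefSeq symbols another 310 and RefSeq synonyms another 687, leaving 95 without a position.

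Alternatives changed the pseudocount, the filter on low values, the scaling, the treatment of the variance, the replicate block and the library left out. The count tests edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. Removing each library's trend on GC content and transcript length, crossing the replicate numbers and leaving the Klk1b genes out of the Leydig list were added after the data were seen. GC content and length of the longest annotated transcript were at hand for 96.19% of tested genes. The pipeline was tested on simulated reads with the means, library sizes and mean-dependent spread of the real libraries and 200 changed genes among 15353 tested. It called 26% of genes changed 1.2-fold, 84% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 6 false calls among 161. With no changed gene it made 0 calls among 15343 tested genes. The simulated genes varied independently, with no trend on GC content between libraries. In the real data, Spearman's rho of the log2 ratio with GC content was 0.335 between the WT libraries. The simulated false calls therefore do not measure the error rate of the real calls.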

Results

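Gene expression in the testis was compared between mice mutant for Lrrc8a and wild-type mice of the FVB strain, with 2 libraries per genotype. Lrrc8a encodes a subunit of the volume-regulated anion channel, which releases chloride and organic osmolytes when cells swell, and the series concerns deficient activity of this channel in male infertility. The libraries held 48409785 (MUT 1), 40426400 (MUT 2), 68192776 (WT 1) and 50162558 (WT 2) reads assigned to genes. Reads were detected for 20169, 20024, 20447 and 20180 symbols in the same order. The 100 most abundant symbols took between 13.9% (MUT 2) and 14.52% (WT 1) of the reads. Across genes, log2 values correlated at 0.9972 between the MUT libraries and 0.9971 between the WT libraries, and at 0.9955 to 0.9963 between genotypes. The replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 5.87 for the MUT pair and 11.6 for the WT pair, against 12 to 16.7 between genotypes, so neither pair was treated as a single library deposited again. This does not show that they came from separate animals.

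Lrrc8a itself was measured at 14.67 ± 1.67 CPM (SD, n = 2) in MUT and 17.68 ± 0.753 CPM in WT testis. Its log2 fold change of -0.26 (SE 0.0998) did not pass the test over all genes (limma adjusted p = 0.218), and the labels do not say which part of the gene the mutation affects. The value depended on single libraries, at -0.15 without MUT 1 and -0.38 without MUT 2. Lrrc8a is a protein-coding gene on the plus strand of chromosome 2, from 30237715 to 30263790 on GRCm38 (ENSMUSG00000007476). It overlaps the antisense gene 1700084E18Rik, whose reads cannot be told apart from those of Lrrc8a if the counting ignored strand. No difference in the other subunits of the family passed the test. Lrrc8b was the most abundant, at 763.9 ± 22.1 CPM in MUT and 759.6 ± 36.7 CPM in WT (log2 fold change 0.01, SE 0.0598). Lrrc8c was at 13.04 and 12.93 CPM, Lrrc8d at 11.63 and 10.45 CPM, and Lrrc8e at 0.9342 and 0.9596 CPM in MUT and WT. None of the 5 was called, and the family did not stand apart from other genes (camera adjusted p = 0.839).

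Of 15364 tested genes, 74 were higher and 41 lower in MUT testis (0.749%), so that 64.3% of the called genes were higher. Most changes were small: the median fold was 1.44 for the higher and 1.34 for the lower genes, and 6 higher and 5 lower genes reached 2-fold. The largest rise was in the zinc finger gene Zfp239, from 0.3087 ± 0.0669 CPM in WT to 9.061 ± 0.869 CPM in MUT (SD, n = 2; log2 fold change 3.56, SE 0.155, limma adjusted p = 6.43e-11). Fibcd1, which encodes a chitin-binding membrane receptor, showed the largest fall, from 5.082 ± 0.448 to 0.8967 ± 0.0794 CPM (log2 fold change -2.00, SE 0.153, adjusted p = 2.49e-07). The count of calls depended on the settings. Without the filter on low values 7 and 4 genes were called, and without the variance trend 5 and 2. The counts were 35 and 18 after quantile normalization, and 46 and 35 after correction for GC content and length. Scaling the recovered reads to their total without the 100 most abundant genes gave 113 and 37 (75.3% higher). That setting also dropped the scaled library sizes of the deposited CPM. It moved the median log2 fold change of all tested genes from -0.0016 to 0.02. DESeq2 on the recovered reads called 94 higher and 72 lower genes, and single libraries mattered too, with 115 and 165 calls without WT 1 and 105 and 89 without MUT 2.

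**Figure D1:**
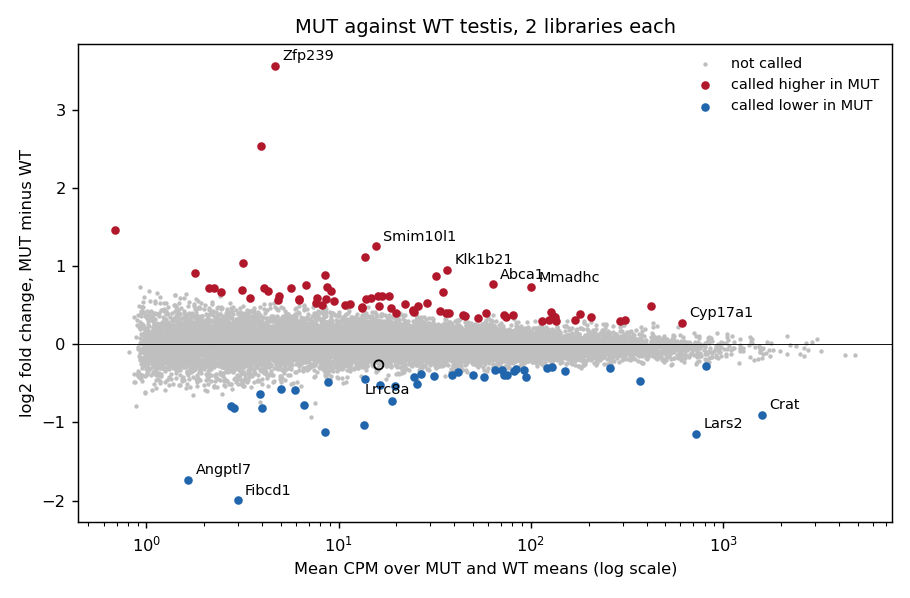
Each point is a tested gene, with its mean CPM on a log axis against its log2 fold change (MUT minus WT, 2 libraries each); red and blue points are the 74 genes called higher and the 41 called lower, and the open circle is Lrrc8a. Zfp239 and Fibcd1 lie farthest from 0 among the genes labelled, and Crat and Lars2 are the most abundant of the called genes labelled as lower.

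Among the other genes with large rises, Smim10l1 went from 9.062 to 22.25 CPM (log2 fold change 1.26, SE 0.106), and Rassf4, of the Ras association domain family, from 1.919 to 4.451 CPM (1.04, SE 0.154). Abca1, the transporter that exports cholesterol to apolipoprotein A-I, rose from 47.01 ± 5.86 to 79.99 ± 5.64 CPM (log2 fold change 0.76, SE 0.0855, limma adjusted p = 6.09e-05). Mmadhc, which acts in intracellular cobalamin metabolism, rose from 75.27 ± 2.08 to 125.2 ± 3.84 CPM (0.73, SE 0.0681, adjusted p = 4.19e-06). Lnpep, Sept14, Cbr2, Rel (an NF-kappa-B subunit) and Zfp449 rose by log2 fold changes of 0.76, 0.73, 0.72, 0.72 and 0.72. Among the falls, Crat, the mitochondrial and peroxisomal carnitine acetyltransferase, was the most abundant, at 2084 ± 55.1 CPM in WT and 1117 ± 47.6 CPM in MUT (log2 fold change -0.90, SE 0.058, adjusted p = 2.25e-08). Crat lies near Lrrc8a, from 30400471 to 30415813 on chromosome 2, and its 3′ end overlaps that of Dolpp1 (30392254 to 30400529), also called lower; Fibcd1 lies on the same chromosome from 31813290 to 31846005. Lars2, the mitochondrial leucyl-tRNA synthetase, fell from 997.8 ± 177 to 447.3 ± 14.7 CPM (-1.15, SE 0.0833), and the microRNA locus Mir6236 from 18.42 to 8.711 CPM (-1.03, SE 0.162). Both were highest in WT 1, at 1123 and 22.31 CPM, against 872.7 and 14.54 CPM in WT 2. Mir6236 is annotated at 123 nt, while the kit selects polyadenylated RNA. Whether reads of other RNAs were assigned to these loci was not tested. Angptl7, which encodes a secreted angiopoietin-like protein, differed in WT between 4.227 and 1.528 CPM and was near 0.43 CPM in MUT (-1.73, SE 0.265). Klrb1, a lectin-like receptor gene of natural killer cells, Klk1b3, Robo3 and Orc4, a subunit of the origin recognition complex, fell by log2 fold changes of -1.12, -0.81, -0.78 and -0.72. Bbc3, a p53 target that promotes apoptosis, Cd74, the invariant chain of MHC class II, and Mfap5, of the elastic microfibrils, had log2 fold changes of -0.64, -0.59 and -0.57. Of these smaller changes, the calls of Rel, Zfp449, Bbc3, Cd74 and Mfap5 were lost in 7, 6, 7, 5 and 7 alternatives. Each was lost when single libraries were left out: Rel and Mfap5 without MUT 1, WT 1 or WT 2, Zfp449 without MUT 2 or WT 2, Bbc3 without MUT 1 or WT 2, and Cd74 without WT 1. The call of Cbr2 was also lost without WT 2 and that of Klk1b3 without WT 1.

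**Figure D2:**
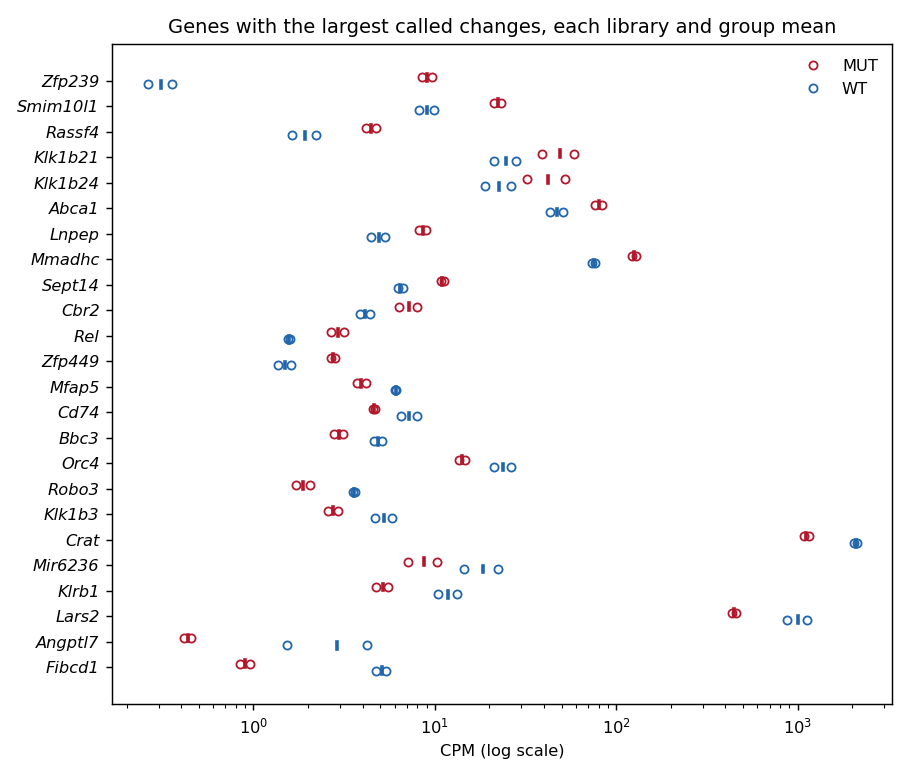
CPM on a log axis of the 24 genes named by size of change, with an open circle for each library and a bar for the mean of the 2 libraries per genotype. The MUT and WT libraries do not overlap for any of these genes, and Angptl7 shows the wide gap between its WT libraries, at 4.227 and 1.528 CPM.

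Genes of Leydig cells, the steroid-producing cells between the tubules, were shifted up in MUT as a list, but not all of them: of 20 tested members, 16 had a log2 fold change above 0 and 4 below, 5 were called higher, 0 lower and 15 not called over all genes, and 13 were higher when adjusted over the list alone. Those below 0 were Sult1e1 (-0.39), Insl3 (-0.28), Scarb1 (-0.07) and Hsd3b6 (-0.01). The MUT and WT libraries overlapped for each of these 4 genes, so their direction is uncertain. Sult1e1 was at 2.829 and 6.963 CPM in MUT and at 6.689 and 5.449 CPM in WT. Insl3 was at 30.22 and 20.21 CPM in MUT and at 23.26 and 39.17 CPM in WT. The called members were Klk1b21, Klk1b24 and Klk1b27 of the tissue kallikrein family, the prolactin receptor gene Prlr, and Cyp17a1, which encodes the 17-alpha-hydroxylase of androgen synthesis. Prlr rose from 23.54 ± 1.39 to 34.32 ± 2.67 CPM (log2 fold change 0.53, SE 0.0874, limma adjusted p = 0.00488) and Cyp17a1 from 552.8 ± 27.9 to 668.6 ± 16.4 CPM (0.28, SE 0.0604, adjusted p = 0.0361). Klk1b21 rose by 0.95 and Klk1b24 by 0.87 on the log2 scale, while their paralog Klk1b3 fell, as given above. Reads of these near-identical genes may be split by the counting, and their libraries spread widely: Klk1b21 was at 39.12 and 58.54 CPM in MUT and at 28.09 and 21.29 CPM in WT. The list's median log2 fold change was 0.283 (camera adjusted p = 6.37e-10; adjusted p = 0.755 with an estimated correlation). With robust variances the adjusted p was 0.251 for Klk1b21, 0.435 for Klk1b24 and 0.0829 for Klk1b27, and DESeq2 called none of these (0.155, 0.337 and 0.28). Cyp17a1 was not called without MUT 1 (adjusted p = 0.0906), MUT 2 (0.16) or WT 2 (0.126), nor Klk1b24 (0.0549) and Klk1b27 (0.0529) without WT 2.

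Genes of Sertoli cells, which nurse the germ cells, were shifted up by less, with a median log2 fold change of 0.102 over 34 members (camera adjusted p = 0.0357; adjusted p = 0.755 with an estimated correlation). Among them Gja1, which encodes the gap junction protein connexin 43, rose from 38.37 ± 1.55 to 49.96 ± 2.38 CPM, and Ptgds, a prostaglandin D synthase gene, fell from 56.91 ± 4.26 to 43.22 ± 0.864 CPM. Each of these calls was lost in 5 of 20 alternatives, that of Gja1 without MUT 1 (limma adjusted p = 0.191) and that of Ptgds without MUT 2 (0.0567) or WT 1 (0.0589). Adjusted over the list alone, 3 members were higher and 1 lower. The list was not called after quantile normalization (adjusted p = 0.0715), by edgeR (0.0565), without MUT 1 (0.362) or without WT 1 (0.1). Genes of peritubular myoid cells, the contractile cells of the tubule wall, lay the opposite way, with a median of -0.156 over 12 members. The camera adjusted p was 0.005 at the preset correlation and 0.763 with the estimated correlation of 0.41. None of the 12 was called over all genes and 4 were lower when adjusted over the list alone, among them Des at 5.389 CPM in WT and 3.702 CPM in MUT and Myh11 at 42.99 and 35.4 CPM. Without WT 1 the adjusted p of this list was 0.208.

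Shifts in the germ cell lists were small. CPM are shares of each library, so a change in the total amount of germ cell RNA need not show in these lists. Of 31 tested genes of elongating spermatids, none was called, 25 had a log2 fold change below 0, and the list's median was -0.078 (camera adjusted p = 0.000731; adjusted p = 0.755 with an estimated correlation). Examples are Tssk6, at 292.7 ± 6.73 CPM in WT and 251.1 ± 1.79 CPM in MUT, and the protamine gene Prm2, at 5108 ± 524 and 4644 ± 170 CPM. This list was not called after quantile normalization (adjusted p = 0.693), without MUT 2 (0.0597) or without WT 1 (0.1). Among spermatogonial genes, 1 of 20 was called: the stem cell factor receptor gene Kit rose from 15.78 ± 1.68 to 21.88 ± 1.71 CPM (log2 fold change 0.46, SE 0.0987, limma adjusted p = 0.0329), a call lost after correction for GC content and length (0.0708), without MUT 2 (0.106) and without WT 1 (0.101), and kept in 14 of 20 alternatives. The spermatogonial list was not called by camera (adjusted p = 0.428), while fry's mixed test, for members changing in either direction, gave an adjusted p of 0.00972. The mixed test does not compare the members with other genes. Of the meiotic prophase (24), pachytene to secondary spermatocyte (25), round spermatid (30) and axoneme and flagellum (29) genes tested, none was called over all genes and none of these lists was called, with camera adjusted p of 0.839, 0.266, 0.641 and 0.378. The most abundant of them included Ldhc, the testis lactate dehydrogenase gene, at 2705 CPM in MUT and 2850 CPM in WT.

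**Figure D3:**
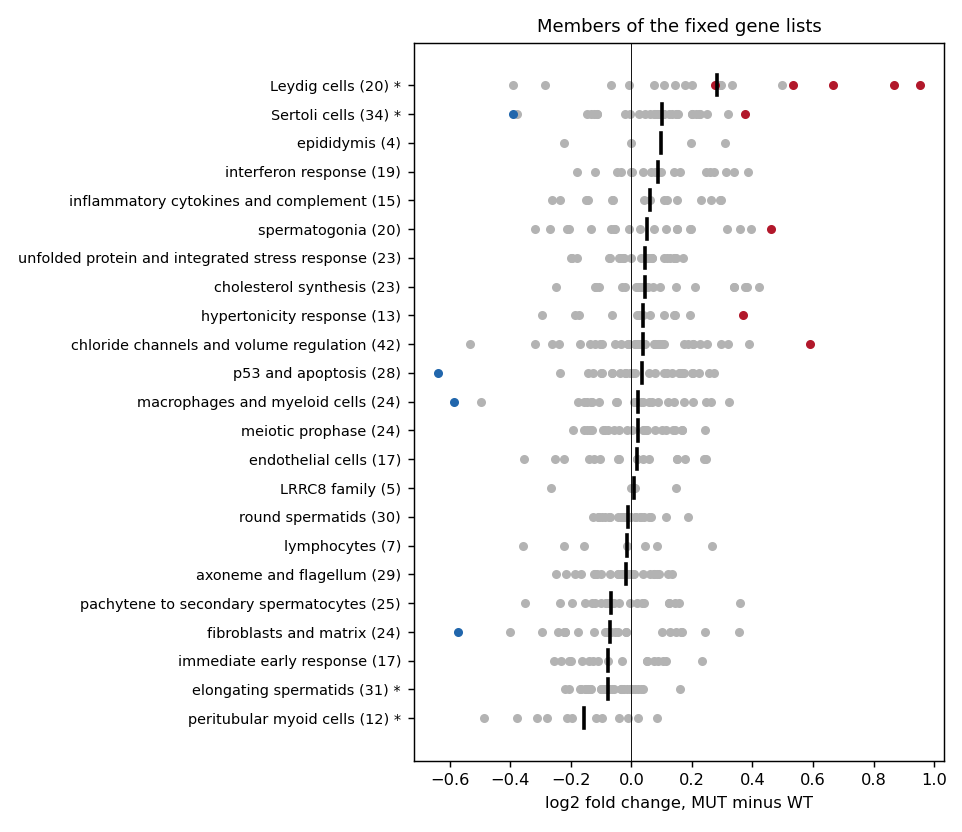
Log2 fold changes (MUT minus WT, 2 libraries each) of the tested members of 23 fixed lists, with member numbers in parentheses and a black bar at each median; red and blue points were called higher or lower over all genes, and an asterisk marks an adjusted camera p under 0.05 at the preset correlation. The Leydig list has the highest median, 0.283, and the peritubular myoid list the lowest, -0.156.

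In the list of chloride channels and volume regulation, 1 of 42 tested members was called, the chloride-proton exchanger gene Clcn5, which rose from 2.665 ± 0.098 to 4.268 ± 0.15 CPM (log2 fold change 0.59, SE 0.136, limma adjusted p = 0.0488). Adjusted over the list alone, 4 were higher and 2 lower, among them the kinase genes Wnk3 (20.73 CPM in WT, 27.31 CPM in MUT) and Wnk1 (539.2 and 630.4 CPM). The list was not called by camera (adjusted p = 0.378), while fry's mixed test, for members changing in either direction, gave an adjusted p of 0.0406. In the hypertonicity list, 1 of 13 was called: Nfat5, the transcription factor of the response to hypertonic stress, rose from 70.81 ± 4.2 to 91.62 ± 8.73 CPM (0.37, SE 0.0779, adjusted p = 0.0321), and the list was not called (0.706). The call of Nfat5 was lost after correction for GC content and length, where its log2 fold change was 0.24 (adjusted p = 0.122), and without MUT 1 (0.326) and WT 1 (0.061), and kept in 13 of 20 alternatives. Clcn5 was called in 5 of the 18 alternatives that gave it a value, and not when any library was left out.

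The remaining lists were not called. Cd74 was the only called member of the macrophage list (24 tested; camera adjusted p = 0.868), Mfap5 of the fibroblast and matrix list (24; 0.223) and Bbc3 of the p53 and apoptosis list (28; 0.641). No member was called in the lists for endothelial cells (17; 0.755), lymphocytes (7; 0.755), epididymis (4; 0.641), unfolded protein and integrated stress response (23; 0.641), interferon response (19; 0.106), inflammatory cytokines and complement (15; 0.744) and immediate early response (17; 0.428), with tested members and camera adjusted p in parentheses. The erythroid list had 1 tested member and the mitochondrially encoded list none, so neither was tested.

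The placement of the called genes was examined after the calls were seen, as were the tests used for it. Within 20 Mb of Lrrc8a, 6 of 285 tested genes were called (2.11%), against 0.724% elsewhere (odds ratio 2.95; two-sided Fisher's exact p = 0.0204); Fibcd1, Crat, Dolpp1, Ptgds and Orc4 were lower there and Zeb2 higher. Within 10 Mb the counts were 4 of 239 (odds ratio 2.3, Fisher's exact p = 0.105), and within 30 Mb 7 of 346 (odds ratio 2.84, Fisher's exact p = 0.0154). Fisher's test treats genes as independent, but Crat and Dolpp1 overlap and may share reads if the counting ignored strand. The call of Zeb2 was lost after correction for GC content and length. The excess rests on few genes and is uncertain. The 20 Mb window with the most called genes lay on chromosome 6 and held 8 of them among 180 tested genes (4.44%, against 0.706% elsewhere), including Zfp239, Rassf4, Klrb1 and Mfap5. Smim10l1 starts at 133104909 on the same chromosome, beyond the end of this window. A window this full was not beyond chance: 538 of 10000 random draws of as many tested genes reached 8 (permutation p = 0.0539), with a median of 6. Dolpp1 and Zeb2, and the genes 4931430N09Rik and Pzp of the chromosome 6 window, were chosen after their values were seen. 4931430N09Rik was at 0.8074 CPM in WT and 7.114 CPM in MUT (log2 fold change 2.54, SE 0.144) and Pzp at 0.1345 and 1.246 CPM (1.46, SE 0.201). The genes called higher also had a lower median GC content than the genes called lower, 44.7% against 56.3%, and longer transcripts, 4680 against 2490 nt. Among the genes called after correction for GC content and length, the medians were 48.7% against 50.3% and 3150 against 3800 nt, so the length difference turned around. It kept its direction among genes called both before and after, at 3270 nt for the 43 higher and 2490 nt for the 25 lower genes.

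**Figure D4:**
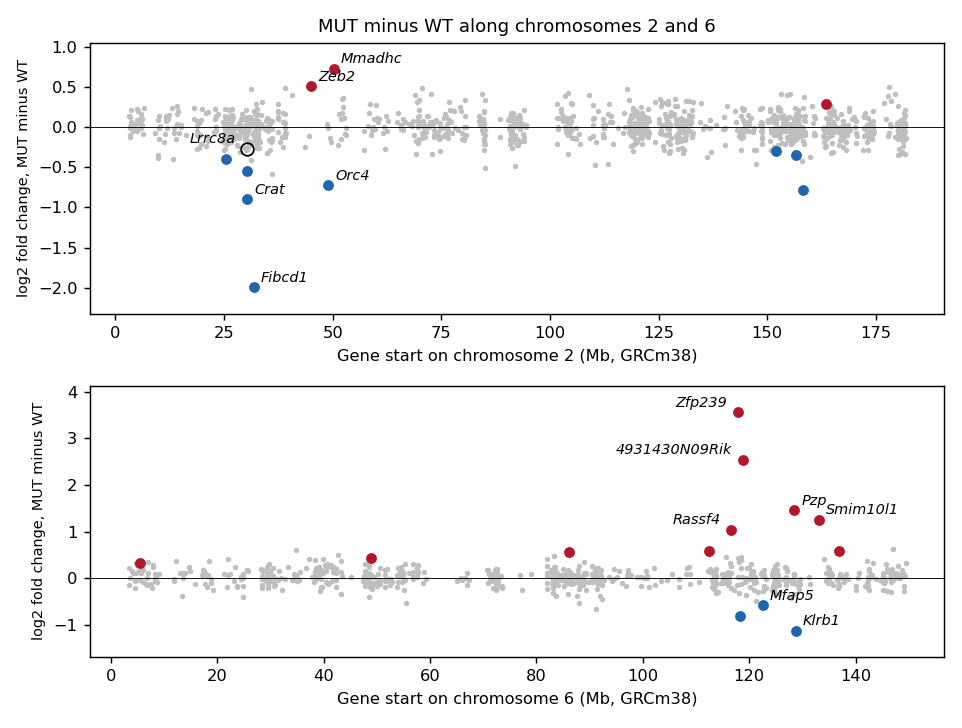
Log2 fold change (MUT minus WT, 2 libraries each) of each tested gene against its start on chromosomes 2 and 6 in Mb of GRCm38; red and blue points are genes called higher or lower, and the open circle is Lrrc8a. The 8 called genes of the fullest 20 Mb window on chromosome 6 start between 112.5 and 128.7 Mb, among them Zfp239 at 3.56.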

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

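The correction for GC content and length, the crossed pairing and the Leydig list without Klk1b genes were tried only after the data were seen. Against 74 higher and 41 lower genes, the counts were 7 and 4 without the filter on low values, 35 and 18 after quantile normalization, 5 and 2 without the variance trend, and 2 and 1 when the log2 fold change had to exceed 1 by the test itself. Scaling without the 100 most abundant genes gave 113 higher and 37 lower, DESeq2 94 and 72, and the GC and length correction 46 and 35, of which 43 and 25 were called before. The cause was not tested. edgeR on the recovered reads called 75 and 41 genes, with 72 and 41 in common with the main test. Leaving out a library in turn, with the lone library of its genotype assumed to vary like the pair of the other, gave 71 to 115 higher and 43 to 165 lower genes, the highest counts without WT 1. The other changes of pseudocount, filter and scaling and the robust variance moved the counts by less than 1.5 times.

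Whether the shared replicate numbers pair the libraries is not stated in the sources used here. Across genes, the deviations of MUT 1 and WT 1 from their group means correlated at -0.134, which gives no sign of pairing. Pairing is not excluded, since the trends on GC content from replicate 2 to 1 ran opposite ways (Spearman's rho -0.0741 in MUT, 0.335 in WT). With the number as a replicate block, 57 genes were higher and 31 lower, 2 lists were higher and 2 lower, and the log2 fold change of Lrrc8a was -0.26. The crossed pairing gave 131 and 104 genes.

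Of the lists, 2 were higher and 2 lower. With an estimated correlation, camera called 0 in either direction (0 at an unadjusted p under 0.05), and fry called 0 (2 at an unadjusted p under 0.05, against 6 for camera with the preset correlation). The lists called at the preset correlation of 0.01 had higher estimated ones, from 0.0237 to 0.41, so correlation between genes can contribute to their lost calls. Correlation was not the sole cause of higher p-values. Cholesterol synthesis was called at neither setting, and its estimated correlation, -0.0177, was below the preset. Its unadjusted camera p still went from 0.0191 to 0.122. Testing for change in either direction, fry gave an adjusted p under 0.05 for 3 lists, spermatogonia (0.00972), cholesterol synthesis (0.00721) and chloride channels and volume regulation (0.0406). Unlike camera, fry does not compare a list with other genes. Of all 15364 tested genes, 1189 higher and 1073 lower had an unadjusted limma p under 0.05. These fry results therefore do not set the lists apart from other genes. Quantile normalization left 1 higher and 1 lower list, and edgeR 1 higher. Leaving out a library gave 1 to 3 higher and 0 to 4 lower lists, with 1 and 0 without WT 1. The Leydig list passed at the preset correlation under each setting tried.

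Lrrc8a stayed below 0 and uncalled in each alternative, from -0.15 without MUT 1 to -0.38 without MUT 2. For 33 named genes, none of 643 values under alternatives changed direction, and 119 lost their call. The MUT and WT libraries did not overlap for any of these genes, so leaving out a library could not turn their direction. Their unchanged directions are therefore no measure of stability. Crat, Smim10l1 and the predicted gene Gm15319 were called in all 20 alternatives fitted across genes; Zfp239 and Fibcd1 were called in the 19 and 18 that tested them. With 2 libraries per genotype, simulated changes of 1.2-fold were called in 26% of cases, so an uncalled gene of this size is not shown to be unchanged.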

Other observations

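In the weighing below, the tests of random placement, of the excess near Lrrc8a, of gaps within the chromosome 6 window, of the spread among Leydig genes, of Leydig against myoid genes, of GC trends between libraries of one genotype and of the GC gap were chosen after the results were seen. The other criteria for the correction for GC content and length were set before its outcome, but the correction itself was added after the data were seen.

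Genes of cholesterol synthesis, not described above, included 5 of 23 tested members that were higher and 1 that was lower when adjusted over the list alone, and none called over all genes. Dhcr7, which encodes a reductase of the last steps of the pathway, was at 40.53 ± 1.56 CPM (SD, n = 2) in MUT against 31.9 ± 1.16 CPM in WT, while Fdps was at 69.17 against 82.36 CPM. The list was not called by camera (adjusted p = 0.0877), while fry's mixed test, for members changing in either direction, gave an adjusted p of 0.00721. All 10 called genes of the X chromosome were higher in MUT, against 64 higher and 41 lower on the autosomes; after correction for GC content and length 3 and 0 X-linked genes were called, and the median log2 fold change of X-linked genes was 0.0577 before and 0.0473 after. A group of called genes, chosen after their values were seen, lies within 19.5 to 21 Mb of chromosome 8: Gm15319 (log2 fold change 1.11), 4930467E23Rik (0.89) and Gm21119 (0.67). They were 3 of 6 tested genes there, all higher, while 2 of the 6 were called after the correction, and may share reads with copies of one another. Malat1, an abundant nuclear non-coding RNA also chosen after its values were seen, was lower in MUT beside Lars2 and Mir6236, at 310.9 against 430.2 CPM.

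The first pattern is the placement of called genes near Lrrc8a and on distal chromosome 6. GC content or transcript length bias is argued against, since 12 of the 13 called genes of both windows that have a GC value were still called after the correction. Chance placement stays open for the fullest window: 0.0539 of 10000 random draws of as many tested genes had a 20 Mb window with at least 8, although 6 of the 11 called genes with at least a 2-fold change lay in the windows (Smim10l1 lies just past the chromosome 6 window), which hold 3.03% of tested genes and were partly chosen for their called genes, so this share was not tested. Sequence differences inherited together with the mutated Lrrc8a are a candidate explanation for the excess on chromosome 2. Its odds ratio was 2.95 within 20 Mb (Fisher's exact p = 0.0204). The odds ratio was 2.3 within 10 Mb (Fisher's exact p = 0.105) and 2.84 within 30 Mb (Fisher's exact p = 0.0154). These tests treat genes as independent, although the overlapping Crat and Dolpp1 may share reads, so the excess itself is uncertain. For chromosome 6, an inherited segment that differs between the animals and a change of expression caused by the mutation cannot be told apart: the median gap between genotypes was 4.05 times the largest gap within one, but the genes were chosen for that gap.

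The second pattern is the rise of the Leydig list, for which GC content or length bias is argued against, since the adjusted camera p was 3.55e-10 after the correction. A lower share of germ cells would raise all somatic markers alike, but Leydig and peritubular myoid genes moved apart, with mean log2 fold changes of 0.263 and -0.168 (two-sided permutation p = 3e-04). The permutation treats genes as independent, although the estimated correlation was 0.108 within the Leydig and 0.41 within the myoid list. Its fold changes were not corrected for GC content. This p therefore does not exclude a lower share of germ cells. A higher share of Leydig cells as the sole cause would raise the members alike, and they differed by more than their limma standard errors (Cochran's Q across genes, n = 20 genes, p = 7.07e-19; n = 17 without the Klk1b genes, p = 6.92e-09). These errors rest on 2 libraries per genotype, and the genes are not independent. Open explanations are a smaller rise in the Leydig share together with changes of single genes, members that are also expressed by other cells, and regulation of Leydig genes in MUT testis, none of which was tested, and with an estimated correlation the list itself was not called (adjusted p = 0.755).

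The third pattern is the GC content of the called genes. A GC trend unrelated to genotype may contribute, since Spearman's rho across genes of the log2 ratio with GC content was 0.335 between the WT libraries and -0.0741 between the MUT libraries, against -0.211 between genotypes. The gap in median GC content between genes called lower and higher was 11.6 percentage points before the correction, 1.6 for the genes called after it and 5.4 for those called both times, but removing the trend shrinks the gap whatever made it, so its origin stays open. The criterion, that most calls stay, was set before the outcome of the correction but after the data were seen. It was met by 66 of the 113 called genes with a GC value, which argues against the trend as the whole cause of the calls. All 47 calls that ended had smaller estimates after the correction (median size 0.433 before and 0.345 after, median standard errors 0.0917 and 0.0898), 24 of them by under 1 standard error, and the prior degrees of freedom also fell, from 16.6 to 11.6.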
